A study of Mus musculus with 12 samples.

How the data were processed

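Ribosome profiling sequences the short mRNA pieces that ribosomes shield from nuclease, so that a count is meant to follow the ribosomes on all copies of a transcript. Levels of mRNA were not analysed here, so fewer ribosomes per copy are not told apart from fewer copies. The libraries came from mouse embryonic stem cells of the V6.5 line, wild type (WT) or lacking Mettl14 (KO), a subunit of the enzyme complex that writes N6-methyladenosine into RNA. Per the labels' protocols, cells were left unheated (noHS), heated at 42 °C for 30 min (HS), or heated and returned to 37 °C for 1 h (recovery). The 6 groups hold 2 libraries each, which the series' design calls biological replicates, 12 in all. Per the labels' protocols, lysates made with cycloheximide were digested with RNase I, short fragments were cut from a gel, and ribosomal RNA was depleted.

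The authors deposited 1 table of raw counts per library, with 61396 transcript IDs in the UCSC known gene style. The tables have the layout of STAR's gene counts, per the file layout: a count on either strand, a count on the transcript's own strand (sense) and a count on the other strand (antisense). Per the submitters' processing notes, STAR, DESeq2 and the mouse build mm10 were used, with no version or role stated. Trimming, the alignment settings, the annotation's version and the filter for ribosomal RNA that the files' labels point to are not given in the sources used here. Counting by transcript sends a read over overlapping transcripts to the ambiguous class, so that a gene with several overlapping isoforms loses counts. The reads in each file, counted or not, numbered 679360 to 2084034. Of these, 36.8% to 55.5% were unmapped, 25.4% to 28.3% mapped to several places, 12.1% to 19.6% lay in no transcript, 1.40% to 13.5% were ambiguous, and 1.26% to 8.75% were assigned to a transcript. These unassigned classes stayed out of library sizes and tests.

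The files do not pair the IDs with gene symbols, and 0 of the IDs matched the table of mouse genes used here, so no gene is named. The 25 gene lists fixed in advance, the level of Mettl14 as a check of the genotype labels, and scaling to mitochondrially encoded genes were for that reason not analysed here. The genotype labels were therefore not checked against the counts. An either-strand count does not tell sense from antisense reads of a transcript. Reads over transcripts that overlap, on the same or opposite strands, are left out of it as ambiguous.

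The planned rule took a stranded column as the main count only if it held at least 5 times the other column in every library. The ratio of sense to antisense counts ran from 0.913 to 1.70, so the either-strand counts were used. Transcripts were kept by filterByExpr with a minimum count of 10, which left 618. Counts were scaled by TMM and tested with edgeR's quasi-likelihood test in 1 fit of the 12 libraries with a coefficient per group and 6 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 618 transcripts, with a threshold of 0.05. The TMM factors ran from 0.296 in WT HS replicate 1 to 6.63 in KO recovery replicate 2. The biological coefficient of variation was 64.1%. TMM left the median of the 618 log2 fold changes away from 0 in each comparison. That median is given with each comparison where transcripts passed the threshold.

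Transcripts were named by a rule fixed in advance: an adjusted p below 0.05, a mean of at least 10 CPM (counts scaled to 1000000 per library after TMM), no overlap between the libraries of the sides compared (within each condition for KO against WT over the 3 conditions, and not required for differences between responses), and the largest change. The rule also asked for protein-coding genes, which could not be applied without names. At most 2 IDs per direction and comparison are given. A fold against a group without a count was computed against a floor of 3 counts over the group and is a lower bound. Intervals of ratios and shares are 95% intervals (Clopper-Pearson for ratios, Wilson for shares). They cover counting error only, since amplified reads are not independent molecules. With a floor of 3 counts, the smallest share of assigned counts that a library could show ran from 0.00164% to 0.0350%.

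After the data were examined, transcripts with at least 50 stranded counts over the 12 libraries were classed by strand: sense-strand transcripts had at least 80% of these on the sense strand, and antisense-strand transcripts at least 80% on the other. Of 573 such transcripts, 405 were sense-strand, 134 antisense-strand and 34 mixed. The 618 tested transcripts held 331, 118 and 29 of these classes, and 140 with fewer counts. Transcripts above 10% of any library's counts in the either-strand, sense or antisense column, 4 in number, were left out of shares by strand. The number of transcripts detected was compared at a fixed depth of 7000 counts, by rarefaction. Library measures were compared by exact two-sided permutation tests within genotype or within condition, 15 tests with Benjamini-Hochberg adjustment.

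The method was tested on simulated counts with the 618 transcripts' means and dispersions for WT HS against WT noHS. Of transcripts raised 4-fold, 8% were recovered, and 68%, 100% and 100% of those raised 16-, 64- and 256-fold. Of those lowered by the same folds, 12%, 56%, 52% and 60% were recovered. Of 418 unchanged transcripts, 1 was called, and 0 of 618 when nothing had changed. The simulation took the fitted scaling as true and changed as many transcripts up as down. It therefore says nothing on false calls that come from the scaling. The replicates of each group differed by far more than sampling noise, with chi-square per degree of freedom from 10.4 to 156, so each library was counted once.

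Alternatives fixed before the data were examined were DESeq2 size factors within edgeR, the DESeq2 Wald test, no filter on low counts, the sense-strand counts, a fit of only the groups compared, the replicate number as a block, and leaving out each library. Alternatives added after seeing the data were scaling to all reads of a library, a fit of sense-strand transcripts alone, leaving out both libraries with under 20000 assigned counts, and a crossed block. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, SciPy 1.17.1, pandas 2.3.3 and NumPy 2.4.6.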

Results

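The series asks how ribosome occupancy of mRNAs changes in mouse embryonic stem cells during heat shock and after it, and whether these changes differ without Mettl14, which is needed to methylate adenosines in mRNA. Heat shock is a stress under which cells make chaperone proteins and reduce the translation of many other mRNAs. Ribosome-protected fragments were counted per transcript in 12 libraries, 2 biological replicates for each of WT noHS, WT HS, WT recovery, KO noHS, KO HS and KO recovery. Counts assigned to transcripts were few and uneven, from 8569 in KO recovery replicate 2 to 182409 in WT HS replicate 1. A single transcript, uc009vev.1, was the largest in all 12 libraries, with 16.3% to 82.7% of the assigned counts, and held at least 50% in 9 of them. In KO recovery its share was 18.2% ± 2.67 (SD, n = 2), against 71.8% ± 2.36 (SD, n = 2) in KO noHS. On the sense strand, uc009vew.1 took 26.0% to 81.0% of the counts, and on the antisense strand uc012hdk.1 took 25.9% to 96.1%. Library by library these counts nearly matched, with 54711 and 55190 in WT noHS replicate 1 and 5580 and 5561 in KO recovery replicate 1. They may be mostly the same reads, over transcripts that overlap on opposite strands, which was not tested. The either-strand counts of these transcripts were 92 and 563 in WT noHS replicate 1. The matching counts also enter the ratio of sense to antisense counts that set the choice of column. These IDs were singled out after their values were seen. Outside the 4 transcripts that took over 10% of some library's counts on either strand, the sense strand or the antisense strand, 7053 to 36987 counts remained per library.

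The share of counts on the transcripts' own strand was lower in both heated groups than in the unheated ones, in a design too small for the test to pass 0.05. Outside these 4 transcripts, the sense share of stranded counts was 70.2% ± 10.8 (SD, n = 2) in WT noHS and 53.7% ± 4.57 (SD, n = 2) in WT HS. In the KO it was 68.9% ± 0.661 (SD, n = 2) in noHS and 48.7% ± 5.44 (SD, n = 2) in HS. After recovery the share was 69.2% ± 10.9 (SD, n = 2) in the WT and 40.8% ± 5.41 (SD, n = 2) in the KO. Within genotype, HS minus noHS was −18.4 percentage points, with an exact two-sided permutation p = 0.0556, the smallest that 36 permutations allow, and an adjusted p = 0.208 over 15 tests. The lowest library, KO recovery replicate 2, had 37.0% (95% Wilson interval 35.9% to 38.1%), and the highest, WT noHS replicate 2, had 77.9% (77.5% to 78.2%). Outside the same 4, sense-strand transcripts received 7362 ± 3057 counts per 1000000 reads in WT noHS, 4024 ± 262 in WT HS and 9274 ± 4903 in WT recovery (SD, n = 2 each). The KO values were 8854 ± 3207 in noHS, 3762 ± 1277 in HS and 2678 ± 511 in recovery (SD, n = 2 each). The left-out sense-strand transcript uc009vev.1 had 31376 and 59521 raw sense counts in WT noHS and 150675 and 9581 in WT HS. These values therefore do not describe the whole class. Outside the same 4, antisense-strand transcripts ranged only from 2850 to 4937 counts per 1000000 reads over the 12 libraries. The antisense-strand transcript among the 4, uc012hdk.1, ranged from 1836 raw antisense counts in KO recovery replicate 2 to 266346 in WT HS replicate 1.

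**Figure D1:**
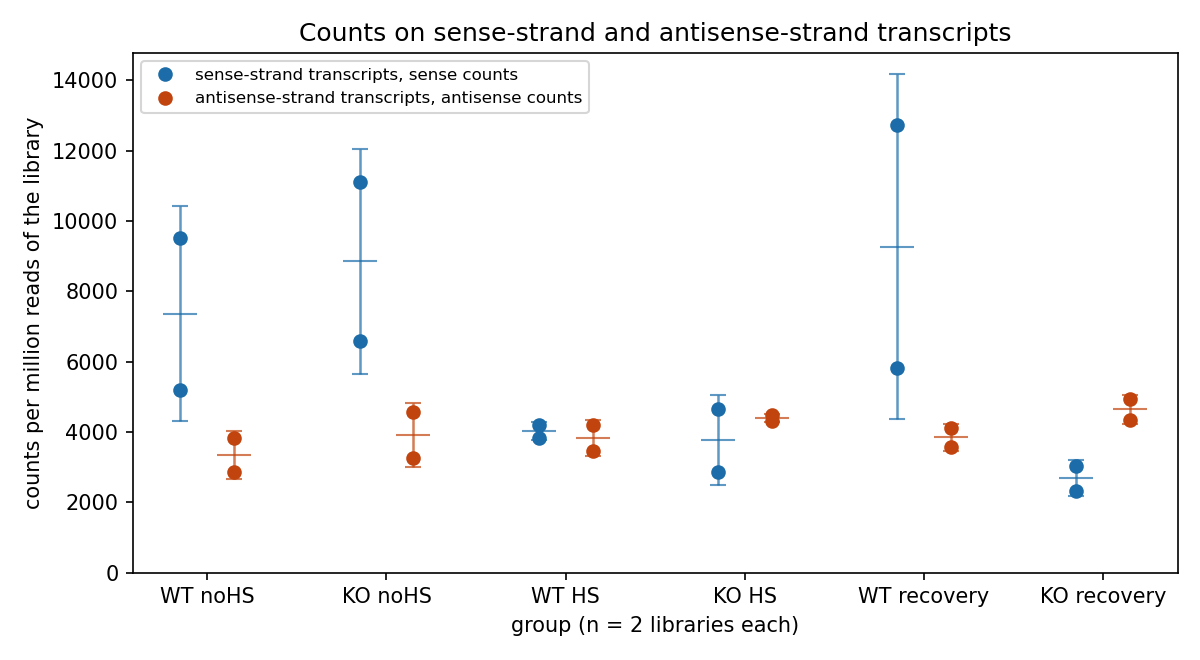
Counts per 1000000 reads of each library (y axis) on sense-strand transcripts (blue) and antisense-strand transcripts (orange) in the 6 groups (x axis); dots are libraries, horizontal marks means and bars ± 1 SD of 2 libraries. The 4 transcripts above 10% of some library's counts, on either strand or 1 of them, were left out. Sense-strand transcripts ran from 2317 to 12741 and antisense-strand transcripts from 2850 to 4937.

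The number of different transcripts detected was also lower in the heated groups, again with too few permutations to pass 0.05. At a fixed depth of 7000 counts outside the 4 transcripts left out above, WT noHS libraries showed 2296 ± 19.2 transcripts and WT HS libraries 1686 ± 40.7 (SD, n = 2 each). KO noHS libraries showed 1986 ± 245 and KO HS libraries 1560 ± 59.7 (SD, n = 2 each). Recovery libraries showed 1949 ± 390 in the WT and 1715 ± 76.2 in the KO (SD, n = 2 each). Within genotype, HS minus noHS was −517.6 transcripts and recovery minus noHS −308.4, each with an exact permutation p = 0.0556, the smallest possible, and an adjusted p = 0.208. Within condition, KO minus WT was −223.3 transcripts, with an exact permutation p = 0.0278 of 216 permutations and an adjusted p = 0.208. The other 11 tests of library measures had adjusted p-values of at least 0.278, and none of the 15 passed the threshold after adjustment. For the 10 tests against noHS this says nothing on whether a difference exists, since their p could not fall below 0.0556.

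In wild-type cells, 60 of 618 transcripts were lower under heat shock than without it and 0 were higher (edgeR quasi-likelihood test, adjusted p below 0.05). Of the 60, 56 were sense-strand transcripts, among 331 tested, and 1 was an antisense-strand transcript, among 118 tested (Fisher's exact test across transcripts, which are not independent replicates, p = 2.3e-07). The strand classes came from the same 12 libraries, so this p is a description and not an independent test. With transcripts that had no count in WT HS, 38 of the 60, set at their bound of 3 counts, the median log2 ratio of the 60 was −4.39 (quartiles −5.20 and −3.26). The fitted median was −6.89, against −0.54 for all 618 transcripts. The transcript uc007pua.1 had 1565 ± 480 CPM in WT noHS and none in WT HS (SD, n = 2 each), at least 49.1-fold lower (edgeR adjusted p = 0.0263). Likewise uc008qmp.1 had 1057 ± 60.6 in WT noHS and none in WT HS, at least 31.6-fold lower (edgeR adjusted p = 0.0263). With WT HS replicate 1 or 2 left out, and so fewer reads to set the floor against, these bounds were 20 or 29.1 and 12.9 or 18.7. The median pooled log2 ratio of sense-strand transcripts was −1.72 (quartiles −3.56 and 0.21), and that of antisense-strand transcripts 0.40 (−0.60 and 0.99). The count of 60 fell to 0 with DESeq2 size factors in edgeR and with scaling to all reads, and to 8 with no filter on low counts, while the DESeq2 Wald test gave 54. It was 115 (111 lower, 4 higher) with the sense-strand counts, 140 (137 lower, 3 higher) with only the groups compared in the fit and 0 without both shallow libraries, those under 20000 assigned counts. It was 0 without either WT noHS or either WT HS library, 31 without either KO noHS library, 142 and 143 without WT recovery replicate 1 and 2, and 15 without KO recovery replicate 2.

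After recovery, wild-type cells showed no transcript past the threshold against either earlier condition. Against WT noHS, edgeR called 0 transcripts, with 27 at an unadjusted p below 0.05, and DESeq2 called 0. Sense-strand transcripts had a median pooled log2 ratio of −0.43 (quartiles −1.14 and 0.30). Against WT HS, edgeR called 0, with 117 at an unadjusted p below 0.05, and DESeq2 called 2, both higher in recovery. Sense-strand transcripts had a median pooled log2 ratio of 1.33 (quartiles 0.12 and 2.70) against WT HS, and antisense-strand transcripts −0.22, which became 0.02 with scaling to all reads. The recovery replicates differed strongly from each other. Across sense-strand transcripts, the Spearman correlation between WT recovery replicates 1 and 2 was 0.301, while replicate 1 correlated at 0.779 with WT HS replicate 1 and replicate 2 at 0.67 with WT noHS replicate 2. Without WT recovery replicate 1, 101 transcripts passed the threshold against WT HS, 100 of them higher in recovery.

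In KO cells, 3 transcripts were lower under heat shock than without it and 0 were higher (edgeR, adjusted p below 0.05). All 3 were sense-strand transcripts, among 331 tested, against none of 118 antisense-strand transcripts (Fisher's exact test across transcripts, p = 0.57). The transcript uc033gpy.1 had 182 counts over the KO noHS libraries, spread unevenly at 1748 ± 2320 CPM (SD, n = 2), and none in KO HS, at least 58.3-fold lower (edgeR adjusted p = 0.0346). That bound rested on KO noHS replicate 2, with 176 of the counts, and was 3.75-fold without it and 116-fold without replicate 1. It was 22.4 or 35.9 without KO HS replicate 1 or 2. The transcript uc033hjs.1 had 352 counts in KO noHS and 6 in KO HS, a ratio of 56.4 (95% counting interval 25.6 to 155, edgeR adjusted p = 0.0346), which was 36.9 without KO noHS replicate 2, and 32.5 or 104 without KO HS replicate 1 or 2. Sense-strand transcripts had a median pooled log2 ratio of −1.82 (quartiles −2.96 and −0.30), and antisense-strand transcripts 0.13 (−0.37 and 0.51). The fitted median of all 618 was −0.80. In all, 126 transcripts had an unadjusted p below 0.05, and the DESeq2 Wald test called 6. The count of 3 became 0 with DESeq2 size factors in edgeR, with scaling to all reads, and without WT noHS replicate 1 or 2, KO noHS replicate 2, either KO HS library or KO recovery replicate 2. It became 1 with no filter and among sense-strand transcripts alone, 5 without both shallow libraries, 54 (53 lower, 1 higher) with only the groups compared in the fit, 7 without either WT HS library, and 56 and 58 without WT recovery replicate 1 and 2.

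The heat shock responses of the genotypes were positively correlated across transcripts. Over the 618 transcripts, which are not independent replicates, the log2 fold changes HS against noHS in KO and WT had a Pearson correlation of 0.639, a Spearman correlation of 0.627 and a slope of KO on WT of 0.477. With no filter on low counts the Pearson correlation was 0.267 and the slope 0.256. No library is shared between these fold changes. All 60 transcripts that fell in WT HS had negative fold changes in KO HS. Most sense-strand transcripts did so too: the fitted median of the 331 tested was −1.92 in KO HS, with an upper quartile of −0.408. Of the 60, 1 passed the threshold in KO HS over all transcripts and 26 when adjusted over the list alone, which was chosen on the WT libraries. With transcripts at 0 counts set at their bound, the median log2 ratio of the 60 was −4.39 in the WT and −2.97 in the KO. The overlap of 1 transcript between the called lists compares with 0.291 for independent lists. The test of the difference between the heat shock responses called 0 of 618 transcripts in edgeR, with 23 at an unadjusted p below 0.05, and 0 in DESeq2. For recovery against noHS, the Pearson correlation was 0.157, the Spearman correlation 0.249 and the slope 0.332. Without WT noHS replicate 2 that Pearson correlation was −0.0834 and the slope −0.154, and without WT recovery replicate 1 they were −0.18 and −0.343. They were 0.42 and 0.701 without WT noHS replicate 1, 0.432 and 0.48 without WT recovery replicate 2, 0.235 and 0.524 without KO recovery replicate 2, and 0.0607 and 0.0781 with no filter on low counts.

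**Figure D2:**
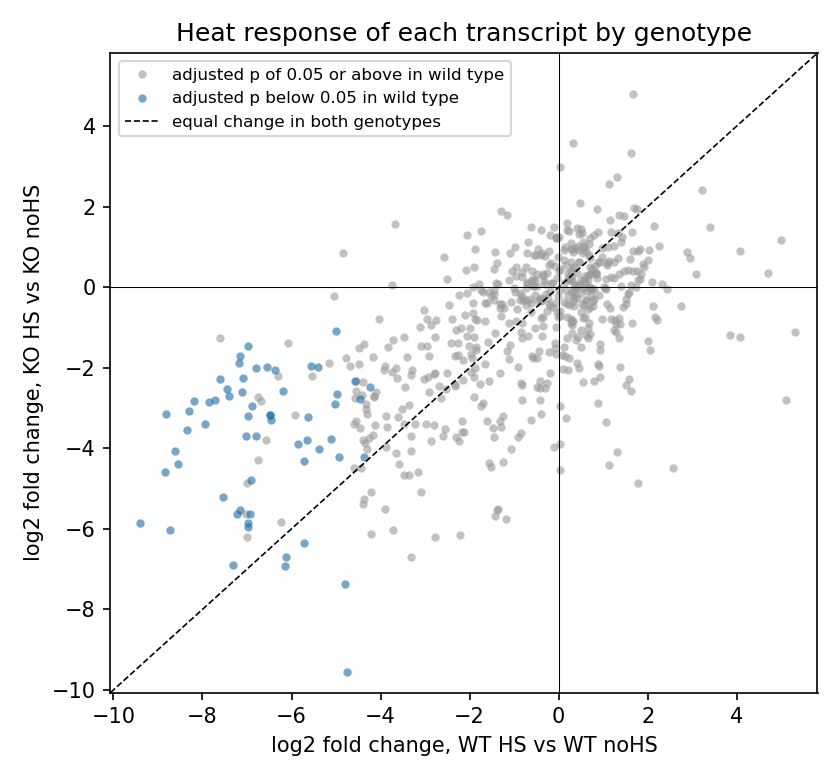
Fitted log2 fold change HS against noHS of each of 618 transcripts in WT (x axis) and KO (y axis); blue dots are the 60 transcripts with an edgeR adjusted p below 0.05 in the WT, and the dashed line marks equal change. All 60 blue dots lie below 0 on both axes. Fitted values of transcripts without counts depend on the prior count.

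In KO cells, recovery libraries had lower counts for many transcripts. Against KO noHS, 142 of 618 transcripts were lower and 0 higher (edgeR, adjusted p below 0.05), of which 131 were sense-strand and 6 antisense-strand transcripts. With the 84 that had no count in KO recovery set at their bound, the median log2 ratio of the 142 was −3.81 (quartiles −5.19 and −3.03), and −2.86 with scaling to all reads. The fitted median was −6.05, against −1.11 for all 618. The transcript uc009vfb.1 had 727 counts in KO noHS and 1 in KO recovery, a ratio of 902 (95% counting interval 161 to 35700, edgeR adjusted p = 0.00202), which was 530 without KO noHS replicate 2. It was 597 without KO recovery replicate 2, and a bound of 102 without replicate 1, which held the only count. The largest transcript, uc009vev.1, whose ID is close, was also lower here (fitted log2 fold change −5.56, edgeR adjusted p = 0.0167). The transcript uc033gpy.1 had 6 and 176 counts in the KO noHS libraries and none in KO recovery, at least 75.3-fold lower (edgeR adjusted p = 0.00609). That bound was 4.84-fold without KO noHS replicate 2 and 149-fold without replicate 1, and 25.4 or 49.8 without KO recovery replicate 1 or 2. Sense-strand transcripts had a median pooled log2 ratio of −2.56 (quartiles −3.88 and −0.85), which was −1.61 with scaling to all reads. For antisense-strand transcripts it was −0.39 and turned to 0.56 with that scaling. These libraries also had the lowest assigned share of reads, 1.26% ± 0.00324, against 7.47% ± 1.26 in KO noHS (SD, n = 2 each). The count of 142 fell to 14 with DESeq2 size factors in edgeR, 17 with scaling to all reads, 33 with no filter and 85 (81 lower, 4 higher) in the DESeq2 Wald test. It was 217 with the sense-strand counts, 63 (60 lower, 3 higher) among sense-strand transcripts alone and 7 without both shallow libraries. It was 79 and 81 without WT noHS replicate 1 and 2, 81 and 64 without KO noHS replicate 1 and 2, and 3 and 0 without KO recovery replicate 1 and 2.

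Against KO HS, 8 transcripts were lower in KO recovery and 0 higher (edgeR, adjusted p below 0.05), with a fitted median of −0.44 for all 618. Of the 8, 7 were sense-strand transcripts and 1 an antisense-strand transcript, among 331 and 118 tested (Fisher's exact test across transcripts, p = 0.687). The transcript uc012cfg.1 had 30 and 146 counts in the KO HS libraries, 2091 ± 2280 CPM (SD, n = 2), and none in KO recovery, at least 75.8-fold lower (edgeR adjusted p = 0.0153). That bound was 21-fold without KO HS replicate 2 and 163-fold without replicate 1, and 25.6 or 50.2 without KO recovery replicate 1 or 2. The transcript uc012fsd.1, at 616 ± 117 CPM in KO HS (SD, n = 2), also had none, at least 28-fold lower (edgeR adjusted p = 0.0296), or 9.46 and 18.5 without KO recovery replicate 1 and 2. The count of 8 was 23 with the sense-strand counts and 15 with only the groups compared in the fit. It was 0 with DESeq2 size factors in edgeR, with scaling to all reads, without both shallow libraries and with no KO recovery replicate 1, KO recovery replicate 2 or WT noHS replicate 1. It was 5 without WT noHS replicate 2, 2 without KO HS replicate 1, and 16 and 17 without WT HS replicate 1 and 2.

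The change from noHS to recovery differed between the genotypes for 36 transcripts, all more negative in the KO (edgeR, adjusted p below 0.05). Of these, 32 were sense-strand transcripts. For uc009vfb.1 the WT libraries had 84 and 177 counts in noHS and 177 and 286 in recovery, while the KO libraries had 219 and 508 in noHS and 1 and 0 in recovery (edgeR adjusted p = 0.00445). For uc011woi.1 the WT libraries had 2 and 64 counts in noHS and 36 and 38 in recovery, and the KO libraries 112 and 63 in noHS and 0 and 0 in recovery (edgeR adjusted p = 0.0145). The fitted median difference of all 618 transcripts was −1.10. The count of 36 was 25 in the DESeq2 Wald test, 0 with DESeq2 size factors in edgeR, 10 with scaling to all reads, 15 with no filter, 57 (2 higher) with the sense-strand counts, 59 (2 higher) with only the groups compared in the fit and 14 without both shallow libraries. It was 0 and 5 without WT noHS replicate 1 and 2, 129 without WT recovery replicate 1, and 11 and 0 without KO recovery replicate 1 and 2.

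In the fit of all 12 libraries with TMM, no transcript passed the threshold between the genotypes without heat shock or under it. Without heat shock, edgeR called 0 of 618 transcripts between KO and WT, with 18 at an unadjusted p below 0.05, and DESeq2 called 0. Fitting only the groups compared gave 6, of which 5 were higher in the KO. The median pooled log2 ratio of sense-strand transcripts was −0.42 (quartiles −1.24 and 0.48). Under heat shock, edgeR called 0, with 26 at an unadjusted p below 0.05, and DESeq2 called 2, both lower in the KO. Without WT HS replicate 2 edgeR called 1, with the sense-strand counts 1, without both shallow libraries 2, and among sense-strand transcripts alone 3. Sense-strand transcripts had a median pooled log2 ratio of −0.21 (quartiles −1.01 and 0.77), which was 0.06 with scaling to all reads. The power to find a difference between the genotypes was not simulated.

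In recovery, 151 transcripts were lower in the KO than in the WT and 0 higher (edgeR, adjusted p below 0.05), 134 of them sense-strand and 5 antisense-strand transcripts. With the 90 that had no count in KO recovery set at their bound, their median log2 ratio was −3.69 (quartiles −5.03 and −2.91), and −3.08 with scaling to all reads. The fitted median was −6.10, against −0.68 for all 618. The libraries also differed in the assigned share of reads, 1.26% ± 0.00324 in KO recovery and 7.12% ± 0.189 in WT recovery (SD, n = 2 each). The largest transcript held 18.2% ± 2.67 and 64.4% ± 13.4 of the assigned counts (SD, n = 2 each). The transcript uc009vfb.1 had 463 counts in WT recovery and 1 in KO recovery, a ratio of 596 (95% counting interval 106 to 23600, edgeR adjusted p = 0.0041), which was 395 without KO recovery replicate 2 and a bound of 67.2 without replicate 1. The transcript uc012cfg.1 had 993 ± 54.1 CPM in WT recovery (SD, n = 2) and none in KO recovery, at least 43.8-fold lower (edgeR adjusted p = 0.00754), or 14.8 and 29 without KO recovery replicate 1 and 2. The count of 151 was 88 in the DESeq2 Wald test, 6 with DESeq2 size factors in edgeR, 33 with scaling to all reads, 24 with no filter, 73 (1 higher) among sense-strand transcripts alone, 13 with only the groups compared in the fit and 9 without both shallow libraries. It was 65 and 60 without WT noHS replicate 1 and 2, 33 without WT recovery replicate 2, and 0 without either KO recovery library.

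Averaged over the 3 conditions, 23 transcripts were lower in the KO than in the WT and 0 higher (edgeR, adjusted p below 0.05), 22 of them sense-strand transcripts. The transcript uc008oan.1 had 87 counts over the 6 WT libraries and 16 over the 6 KO libraries, a pooled ratio of 6.02 (95% counting interval 3.5 to 11, edgeR adjusted p = 0.0485). The transcript uc007icc.1 had 39 and 13 counts, a pooled ratio of 3.32 (1.73 to 6.78, edgeR adjusted p = 0.0485). Its 13 KO counts were 7 and 6 in the noHS libraries and none in HS or recovery, and the ratio was 6.04 and 5.22 without KO noHS replicate 1 and 2. The fitted median log2 fold change of the 23 was −0.59 in noHS, −2.02 in HS and −6.99 in recovery, and of all 618 the median over conditions was −0.38. The count of 23 was 31 in the DESeq2 Wald test, 0 with DESeq2 size factors in edgeR and with scaling to all reads, 2 with no filter and 3 without both shallow libraries. It was 0 without WT noHS replicate 1 or 2, KO noHS replicate 1, WT HS replicate 1 or either KO recovery library, and 2 without KO noHS replicate 2 or KO HS replicate 2. It was 36 without WT HS replicate 2, and 75 and 12 without WT recovery replicate 1 and 2.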

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

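Fixed after the data were examined were the strand classes, the fit of sense-strand transcripts alone, the scaling to all reads, and the reading of the test that left out the shallowest library. The 36 transcripts whose change from noHS to recovery was more negative in KO than in WT cells met the test of a difference between groups. The antisense share of stranded counts in KO recovery, 59.2% ± 5.41 outside the 4 transcripts with over 10% of some library's counts, on either strand or 1 of them, against 31.1% ± 0.661 in KO noHS (SD, n = 2 each), comes from the antisense column, which the tests of single transcripts did not use. Its complement, the sense share, was among the library measures tested: recovery minus noHS, averaged over both genotypes, was −14.5 percentage points (exact permutation p = 0.111, adjusted p = 0.278). That test could not have passed, since the smallest p of its 36 permutations is 0.0556, and the KO share alone was not tested.

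The first pattern weighed is the 142 transcripts lower in KO recovery than in KO noHS. With each library scaled to all its reads, their fitted median log2 fold change was −5.66 (quartiles −6.43 and −4.59), against −6.05 before. These transcripts were chosen for their falls, and 84 had no count in KO recovery, so rescaling could hardly have removed the fall. The test therefore cannot decide whether scaling was a source of the fall. The fitted median of all tested transcripts, not chosen this way, moved from −1.11 to −0.157 with that scaling. Only 17 of the 142 were still called, with a median standard error of 2.04 against 1.8 and a median adjusted p of 0.113 against 0.0197. With DESeq2 size factors 14 were still called at a median standard error of 1.9. The calls do rest on the scaling, and the cause of their loss was not tested. A loss common to all sense-strand transcripts stays open: after scaling among these alone, 45.8% of the called sense-strand transcripts (60 of 131) were still called lower. The median of the 131 was −5.55 (quartiles −6.29 and −4.39), against −6.12 before, so calls were lost more than the fall. The shallowest library stays open as well: without KO recovery replicate 2, 0% of the 142 were still called, with a median of −5.84, but without replicate 1 it was 2.11%, so the test, which had been meant to point to the shallow library, was not specific to it. A response of cells without Mettl14 to recovery stays open too, untested beside the low share of assigned reads in both KO recovery libraries.

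The second pattern is the 60 transcripts lower in WT HS than in WT noHS. After scaling among sense-strand transcripts alone, 96.4% of the called sense-strand transcripts (54 of 56) were still called lower. The median of the 56 was −6.56 against −6.92. These transcripts were chosen for their falls, and 38 of the 60 had no count in WT HS, so rescaling could hardly have removed the fall. The test therefore cannot decide whether a loss common to all sense-strand transcripts was the source. With scaling to all reads the fitted median of the 60 was −6.85 (quartiles −7.39 and −5.81), against −6.89, yet 0 of 60 were still called. Their median adjusted p was 0.0801 against 0.0351, at a median standard error of 1.94 against 1.93, and why p rose was not tested. Without WT HS replicate 2, the shallower library, 0% of the 60 were still called, with a median of −7.01, and leaving out any other library of the comparison also left 0%, so depth as a source stays open. Heat shock itself remains a possible explanation, untested beyond these comparisons.

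The third is the 23 transcripts lower in KO than in WT over the 3 conditions. Of 100 splits of the libraries within conditions, the real one included and drawn from 108, 9 gave at least as many transcripts, so chance could not be excluded. The highest of the other splits gave 99, several times the real count. Of the 99 other splits, 30 kept the recovery libraries apart by genotype and regrouped the other conditions, and all 8 that gave as many transcripts were among these 30, against 0 of the 69 that mixed the genotypes in recovery. The large counts thus went with the difference between the genotypes in recovery, a comparison made after the splits were seen. The higher of the medians of the 23 in noHS and in HS was −0.587, between the bounds set for a pattern carried by recovery alone and for one present in each condition, so that question stays open.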

How the results depend on the processing

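Scaling to all reads, the fit of sense-strand transcripts alone, leaving out both shallow libraries and the crossed block were chosen after seeing the data; the others were fixed in advance. No alternative turned the direction of a named transcript: of 294 refits of 14 named results, 188 kept direction and side of the threshold, 106 lost the call and 0 changed sign. The naming rule chose the largest changes, mostly without overlap between the sides, so a change of sign could hardly occur. The kept signs are therefore no measure of stability. The counts moved far more, and beyond the fewer samples or other transcripts in some fits the cause was not tested. The limits are depth, with 7053 to 36987 counts per library outside the 4 transcripts left out, and 2 libraries per group.

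The counts that moved, in the order WT HS, KO HS and KO recovery (each against noHS), KO recovery against KO HS, then KO against WT in recovery and over conditions, then the difference in recovery response, were 60, 3, 142, 8, 151, 23 and 36. DESeq2 size factors gave 0, 0, 14, 0, 6, 0 and 0, scaling to all reads 0, 0, 17, 0, 33, 0 and 10. No filter gave 8, 1 and 33, then 24, 2 and 15, with the fourth within 1.5 times. Leaving out both shallow libraries gave 0, 5, 7, 0, 9, 3 and 14, and 2 for KO against WT under heat shock. The DESeq2 Wald test gave 6 for KO HS, 85 for KO recovery, 88 for KO against WT in recovery, 2 for WT recovery against WT HS and 2 for KO against WT under heat shock. The sense-strand counts gave 115 for WT HS (4 higher), 217 for KO recovery, 23 against KO HS, 1 for KO against WT under heat shock and 57 for the difference in recovery (2 higher). Fitting only the groups compared gave 140 for WT HS, 54 for KO HS, 15 for KO recovery against KO HS, 6 for KO against WT without heat, 13 in recovery and 59 for the difference in recovery. Sense-strand transcripts alone gave 1 for KO HS, 63 for KO recovery (60 lower, 3 higher), 3 for KO against WT under heat shock and 73 in recovery.

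The replicate numbers did not pair the libraries: over 15 pairs of groups, deviations of same-numbered libraries correlated from −0.251 to 0.384. With the replicate block the counts were 1 for WT HS, 0 for KO HS, 83 for KO recovery, 0 against KO HS, 50 for KO against WT in recovery, 2 over conditions and 18 for the difference in recovery; the block changed no other count of transcripts. The crossed block for WT HS gave 1.

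Leaving out 1 library at a time, with a lone library assumed to vary like the other groups, gave 0 to 143 for WT HS, 0 to 101 for WT recovery against WT HS, 0 to 58 for KO HS, 0 to 210 for KO recovery and 0 to 17 against KO HS. For KO against WT it gave 0 to 1 under heat shock, 0 to 218 in recovery and 0 to 75 over conditions, and 0 to 129 for the difference in recovery. The Pearson correlation of the heat shock responses ran from 0.524 to 0.67 and the slope from 0.364 to 0.536, and with no filter they were 0.267 and 0.256. For recovery they ran from −0.18 to 0.432 and from −0.343 to 0.701; without WT noHS replicate 2 they were −0.0834 and −0.154. Scaling to mitochondrial genes and the tests of gene lists were not run, because the IDs were not matched to genes.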

Other observations

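The following tests and groupings were all chosen after the data were seen. Outside the 4 transcripts with over 10% of some library's counts, counts on antisense-strand transcripts varied little between libraries while counts on sense-strand transcripts varied much. Over the 12 libraries the SD of log2 counts per 1000000 reads was 0.23 for antisense-strand and 0.786 for sense-strand transcripts, a ratio of 0.292. The left-out antisense-strand transcript uc012hdk.1 held 25.9% to 96.1% of the antisense counts and was not steady, with 1836 in KO recovery replicate 2 and 266346 in WT HS replicate 1. A candidate explanation is that the antisense-strand counts outside the 4 transcripts hold fragments that are not ribosome footprints. These would make up a steady part of every library, so that the sense share falls when footprints become fewer. The ratio restates the observation that prompted this hypothesis and so does not test it, the strand classes came from the same libraries, and no fragment lengths or reading frames were analysed here.

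The IDs of transcripts that fell in WT HS were not spread evenly. Of 16 tested sense-strand transcripts whose ID begins with uc007p, 10 were lower in WT HS than in WT noHS, against 46 of 315 others (one-sided Fisher's exact test across transcripts, p = 3.24e-05, adjusted p = 0.00234 over 72 tests). In KO recovery against KO noHS it was 9 of 16 against 122 of 315 (adjusted p = 1), and in KO recovery against WT recovery 8 of 16 against 126 of 315 (adjusted p = 1). Of 8 such transcripts whose ID begins with uc009v, among them uc009vev.1 and uc009vfb.1, 7 were lower in KO recovery than in KO noHS. The others had 124 of 323 lower (one-sided Fisher's exact test, adjusted p = 0.15). Whether the transcripts of these prefixes overlap or are alike in sequence was not tested, and the files do not pair them with genes.

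Across sense-strand transcripts, the 12 libraries did not fall together by group alone. WT recovery replicate 2 had Spearman correlations of 0.559 and 0.67 with the WT noHS libraries and of 0.227 and 0.146 with the WT HS libraries. WT recovery replicate 1 had 0.229 and 0.087 with WT noHS, and 0.779 and 0.638 with WT HS. The KO recovery libraries correlated with each other at 0.727 and with the KO HS libraries at 0.588 to 0.692. With the WT HS libraries they correlated at 0.464 to 0.714.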
